A study of Mus musculus with 6 samples.

How the data were processed

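Gene expression was measured on 6 Affymetrix arrays, each hybridised with RNA from a sorted bone marrow fraction of a mouse. The animals were 3 Grem1;TdTomato reporter mice aged 6 to 8 weeks that received tamoxifen by mouth. Per the labels' protocols, total RNA was extracted with the RNAqueous-Micro kit, amplified with the NuGEN Ovation One-Direct System and labelled with biotin. The deposited values are log2 expression values per probe set, and the submitters' processing notes name GCRMA, which corrects background from probe sequence, normalizes the arrays and summarises probes. Its version and settings are not given in the sources used here, and the log2 scale was read from the values, which ran from 0.798 to 14.05. The scanner files were not analysed here, so background correction could not be repeated.

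The table held 45101 probe sets, of which 64 were control probe sets. Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 were unnamed here. Probe sets with several symbols or none were not tested. Entrez identifiers of 34741 named probe sets were found in a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols. No genome was used here and no coordinates are given. A probe set entered the tests when its log2 value was above 4 on at least 3 of the 6 arrays, which 21605 probe sets met, 18157 of them named. For each gene the passing probe set with the highest mean was used, which left 10151 genes. Other passing probe sets of a gene could differ by less, and their range is not given for every gene.

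Arrays were grouped by the cell type in the labels into Grem1+ and Grem1- with 3 arrays each. The series design text states that both fractions came from the same mice, and the number in each title was taken as the mouse. Deviations from the group means, compared across genes between arrays of the same number, correlated at 0.014, 0.074 and 0.046 for mice 1, 2 and 3, so the pairing rests on the design text and not on these correlations. No pair of arrays shared more than 0.00222% of probe set values to 6 decimals.

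Differences are Grem1+ minus Grem1-. They were tested with limma 3.58.1 (lmFit and eBayes at default settings, R 4.3.3) with the mouse as a block, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 10151 genes, with a threshold of 0.05. The fit had 2 residual and 2.10 prior degrees of freedom. The number of arrays limits the precision. A value below log2 4 was treated as dim. That limit was chosen and is not a measured detection limit. Where a gene passed the threshold and every array of its lower group was dim, the difference is given as a bound with dim values set to log2 4. Where such a gene did not pass, the difference with that floor is given. Another 54 named genes past the threshold had only some dim arrays in the lower group and are given as measured, and the floor reduced their log2 differences by at most 1.31.

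The 34 gene lists of cell type markers and pathway members, the filter, the test and the naming rule were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so few lists could pass whatever their correlation. Lists with an estimate below the preset, such as B lineage at -0.058 and fibroblast and tendon at 0.00098, also did not pass. Other lists had estimates above the preset, such as chondrocyte at 0.121, osteoblast at 0.141, pan-haematopoietic at 0.158 and granulocyte at 0.335. For such lists the camera p-values at the preset may be too small. The naming rule took Grem1, Ptprc and Pecam1, then the 10 genes with the largest difference in each direction among those past the threshold with the same sign in all 3 mice. From each list it took up to 4 members past the threshold with the largest absolute difference, or up to 2 measured members where none passed. A name outside this rule was chosen after its values were seen, and those are Sox9, Acan, Col10a1, Col2a1, Col9a3, Sox6, Col1a1, Col3a1, Cxcl12, Lepr, Sp7, Hp, S100a4, Acvrl1, Tgfb1, Il1b, Mt2, Xist, the Y-linked genes and the genes of the families in the closing section.

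The tests were tried on simulated data of the same 10151 genes with 200 genes changed. They recovered 0% of genes changed by log2 1, 32% at log2 2, 92% at log2 4 and 100% at log2 6, and called 9 unchanged genes. With no gene changed they called 0. With the 2055 called genes set to their own estimated differences and spreads, 95.5% were recovered and 4.29% of the calls fell on unchanged genes. These genes had been chosen for passing, so this recovery is no independent measure of sensitivity. The simulated noise was drawn independently for each gene, so these shares need not hold for the real arrays. Alternatives were a fit with no replicate block, other filters and choices of probe set, other normalizations, a floor at log2 4, other variance settings, array weights and leaving out each mouse. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.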

Results

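Bone marrow of 3 tamoxifen-treated Grem1;TdTomato mice was digested and sorted into a Grem1+ fraction, which the labels describe only as sorted for Grem1, and a Grem1- fraction. Grem1 encodes Gremlin 1, a secreted antagonist of bone morphogenetic proteins. The Grem1- fraction was non-recombined and sorted as negative for CD45, CD31 and Ter-119, antigens of blood, endothelial and erythroid cells, and the labels state this gate only for that fraction. Each fraction of each mouse was hybridised to an array, giving 3 arrays per group. Array medians ran from 3.74 to 3.81 on the log2 scale, and 44.9 to 45.5% of probe sets lay above log2 4 on each array. Across probe sets, arrays correlated at 0.939 to 0.946 within Grem1-, at 0.902 to 0.922 within Grem1+ and at 0.793 to 0.846 between the groups, where probe sets are not independent replicates. The 3' minus 5' difference of the Gapdh control, which grows as RNA shortens, was 2.66 ± 0.34 in Grem1- and 3.58 ± 0.51 in Grem1+ (log2, SD, n = 3), and that of actin was 0.16 ± 0.02 and 0.09 ± 0.11. Within each of the 3 mice the Gapdh value was higher in Grem1+ and the actin value was lower. The labels record all animals as male, but Xist, the transcript of the inactive X chromosome, was at 11.04 and 10.60 in the 2 fractions of mouse 3 and at or below 2.99 on the other 4 arrays.

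The comparison asked which transcripts distinguish Grem1+ cells from other marrow cells outside the gated lineages. Of 30 measured chondrocyte genes 27 were higher in Grem1+, and of 22 pan-haematopoietic genes 18 were lower. Of 10151 genes tested, 1191 were higher and 864 were lower in Grem1+, 20.2% in all. All 2055 had the same sign in each of the 3 mice, which passing the threshold with 3 pairs all but requires. With values below log2 4 set to 4, 255 of the higher and 119 of the lower genes differed at least 16-fold. The 10 genes with the largest positive difference included Speg, a kinase of striated muscle, at 7.97 (SE 1.06), whose Grem1- arrays stood at 6.70, 2.25 and 1.83 and whose 4 passing probe sets ranged from 0.60 to 7.97. With values below log2 4 set to 4 Speg stood at 6.67, under C1qtnf3 at 7.65, and without the filter on dim probe sets it lost its call (adjusted p = 0.0521). C1qtnf3, a secreted protein of the C1q and TNF-related family, differed by 7.89 (SE 0.48), and Fscn1, an actin-bundling protein, at 7.64 (SE 0.30). Susd5 was higher by 7.16 (SE 0.30). The 6 other genes of the top 10 had every Grem1- array below log2 4, so only bounds are given. Panx3, a pannexin channel, was at least 121-fold higher, Nckap5 at least 83.4-fold, Hs3st3a1, a heparan sulfate sulfotransferase, at least 74.2-fold, Prkd1 at least 63.7-fold, Phyhipl at least 41.4-fold and Pkdcc at least 35.5-fold. Without probe sets that other transcripts may share, Panx3 stood at 1.97 and lost its call (adjusted p = 0.160), and Prkd1 stood at 3.91. With the mean of a gene's probe sets, Speg stood at 3.36, Fscn1 at 4.67, Pkdcc at 3.93 and Panx3 at 4.56, all still past the threshold.

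Of the 10 genes with the largest negative difference, Hemgn, a nuclear protein of erythroid cells, was at least 76.3-fold lower in Grem1+, and Vpreb1, a surrogate light chain of B cell precursors, at least 65.7-fold lower. Insyn2b and 4933431G14Rik were at least 42.8-fold and 31.9-fold lower. AI467606 differed by -7.27 (SE 1.40), Gca by -7.10 (SE 0.90), and Car2, carbonic anhydrase 2, by -6.78 (SE 0.71). Atp8b4 differed by -6.36 (SE 0.90), Ncf1, a subunit of the phagocyte NADPH oxidase, by -6.28 (SE 0.46), and St8sia4 by -6.28 (SE 0.80). Some Grem1+ arrays were dim, and with values below log2 4 set to 4 AI467606 differed by -6.35, Gca by -6.15, Car2 by -6.35, Atp8b4 by -5.21 and St8sia4 by -5.68. The adjusted p-values of these 20 genes in limma were at most 0.0379. With the mouse block kept and any mouse left out, limma called 0 genes in either direction, while 3018, 2919 and 2881 genes had an unadjusted p under 0.05. Without the filter on dim probe sets, 31 of the 120 named list and top genes past the threshold lost their call, among them AI467606 (adjusted p = 0.0984) and Atp8b4 (adjusted p = 0.0569). Without the block, leaving out mouse 1, 2 or 3 gave 767, 764 and 769 higher and 507, 422 and 525 lower genes, an alternative chosen after seeing the data.

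**Figure D1:**
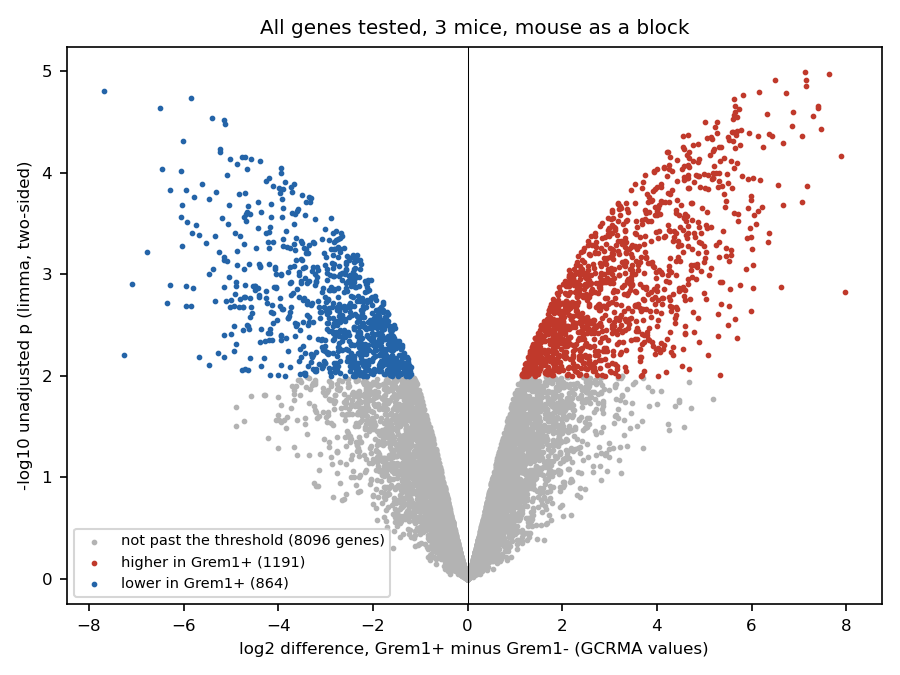
Each point is a gene, with the log2 difference of Grem1+ minus Grem1- on the x axis and the -log10 unadjusted p of limma with the mouse as a block on the y axis. Red points are the 1191 genes higher in Grem1+ and blue points the 864 lower genes past the adjusted threshold.

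The sorted marker and the gate antigens were examined first as a check of the labels. The mice carry a reporter allele, so the Grem1 transcript may or may not follow the sorted reporter. Grem1 averaged 3.71 ± 0.03 in Grem1- and 5.75 ± 2.48 in Grem1+ (log2, SD, n = 3). The 3 Grem1+ arrays stood at 4.49, 4.14 and 8.61, each above its Grem1- partner. The difference of 2.04 (SE 1.04) did not pass the threshold (limma adjusted p = 0.248), and it was 0.60 without mouse 3 and 1.75 with values below log2 4 set to 4. Ptprc, the gene of CD45, averaged 12.09 ± 0.30 in the Grem1- fraction, despite its gate, and 9.15 ± 1.68 in Grem1+, where the arrays stood at 7.29, 9.61 and 10.56. The difference of -2.94 (SE 0.71) did not pass (limma adjusted p = 0.0609), but its second probe set, at 8.37 to 9.38 in Grem1- and below log2 4 on all Grem1+ arrays, was at least 28.9-fold lower and passed when chosen (adjusted p = 0.0105). Pecam1, the gene of CD31, averaged 4.80 ± 0.52 and 3.30 ± 0.45, a difference of -1.50 (SE 0.36) that did not pass either (adjusted p = 0.0587) and was -0.80 with values below log2 4 set to 4. Without the replicate block, Ptprc and Pecam1 passed at adjusted p-values of 0.0442 and 0.0357, and over all alternatives these ranged from 0.0103 to 0.163 for Ptprc and from 0.0281 to 0.217 for Pecam1.

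**Figure D2:**
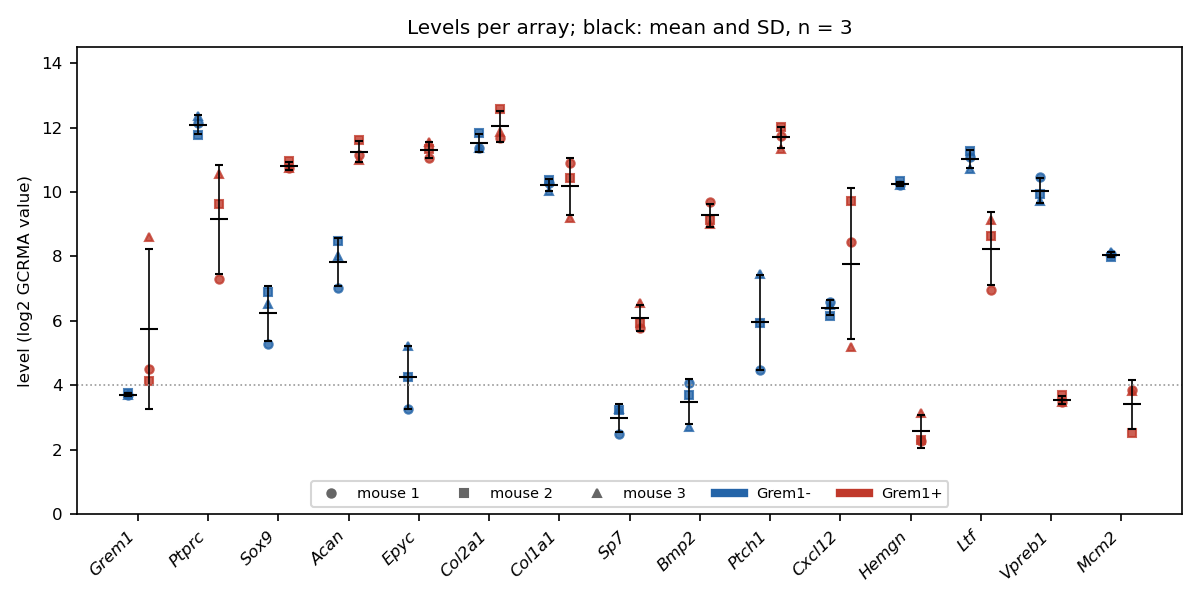
Log2 GCRMA values (y axis) of 15 genes (x axis) on each array, in blue for Grem1- and red for Grem1+, with a symbol for each mouse and black bars for the mean and SD of 3 arrays. The dotted line marks log2 4. Grem1 lies below it on the 3 Grem1- arrays and reaches 8.61 only in mouse 3, while Ptprc is at 11.78 or above on the Grem1- arrays.

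Genes of cartilage were higher in Grem1+ nearly throughout. Of 30 measured chondrocyte genes, 27 were higher and 0 lower, and 28 and 0 when adjusted over the list alone. The median difference was 3.66 (camera adjusted p = 2.56e-15, and adjusted p = 0.234 with an estimated correlation). Epyc, a small leucine-rich proteoglycan of cartilage, went from 4.25 ± 0.98 in Grem1- to 11.31 ± 0.25 in Grem1+, a difference of 7.06 (SE 0.39). Cytl1 differed by 6.87 (SE 0.33), Ucma by 5.93 (SE 0.41) and Matn1, which encodes matrilin 1, by 5.64 (SE 0.37). Sox9, the master transcription factor of cartilage, was higher by 4.58 (SE 0.39), Col10a1, the collagen of hypertrophic cartilage, by 4.65 (SE 0.32), and Acan, the gene of aggrecan, by 3.42 (SE 0.35). The 3 members that did not pass were Col2a1, at 11.52 ± 0.28 and 12.04 ± 0.47 with a difference of 0.52 (SE 0.26), Col9a3, with 1.08 (SE 0.42), and Sox6, with 2.03 (SE 0.48). On the same arrays, the granulocyte list had median levels of 10.04, 10.30 and 10.24 in Grem1- and of 4.98, 5.95 and 7.11 in Grem1+. Against 87 other genes of the osteoblast, fibroblast, niche, smooth muscle and adipocyte lists, whose median difference was 1.44, the chondrocyte median was further from 0 by 2.12, 2.02 and 2.24 in mice 1, 2 and 3. Against the osteoblast list alone this gap was 0.87, 1.31 and 1.31.

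Bone, fibroblast and basement membrane genes were also higher as groups. Of 18 osteoblast genes, 9 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 2.48 (camera adjusted p = 6.48e-06, and adjusted p = 0.253 with an estimated correlation). Pth1r, the receptor of parathyroid hormone, was higher by 5.14 (SE 0.47), Smpd3 by 4.24 (SE 0.32), Dlx5 by 3.76 (SE 0.39) and Ibsp, bone sialoprotein, by 3.48 (SE 0.41). Col1a1, a main collagen of bone, stood at 10.22 ± 0.18 and 10.18 ± 0.88. Of 26 fibroblast and tendon genes, 12 were higher and 1 lower (12 and 2 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 0.000367, and adjusted p = 0.234 with an estimated correlation). Fap differed by 6.13 (SE 0.51), Col6a1 by 5.01 (SE 0.25), Cilp, a cartilage matrix protein, by 4.67 (SE 0.34) and Col6a3 by 4.66 (SE 0.32), and the lower gene was S100a4 (-1.30, SE 0.29). Col3a1, at 10.56 ± 0.46 and 10.52 ± 0.73, did not pass. Of 21 genes of basement membrane and matrix receptors, 10 were higher and 1 lower, with the same counts adjusted over the list alone, and the median was 1.43 (camera adjusted p = 0.000621, and adjusted p = 0.234 with an estimated correlation). Nid2 was higher by 5.56 (SE 0.59), Itga5, a fibronectin receptor subunit, by 3.73 (SE 0.44), Hspg2, the gene of perlecan, by 2.60 (SE 0.31) and Col4a5 at least 5.23-fold. The lower gene was Itgb3 (-1.62, SE 0.27). Without shared probe sets Hspg2 stood at 1.16 and lost its call (adjusted p = 0.143), Itga5 stood at 2.44 with the mean of its probe sets, and without the filter on dim probe sets the fibroblast median was 0.86. With the stricter filter the basement membrane median was 2.33. Ptprc was at 12.09 in the Grem1- arrays from which these differences were taken.

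Lists of niche stroma and progenitors went both ways. Of 21 genes of the stroma that supports haematopoietic stem cells, 7 were higher and 2 lower (9 and 3 adjusted over the list alone), with a median of 1.60 (camera adjusted p = 0.0212, and adjusted p = 0.401 with an estimated correlation). Chrdl1, a BMP antagonist, differed by 6.13 (SE 0.33), and its 4 passing probe sets ranged from 2.83 to 6.13. Igf1 differed by 3.72 (SE 0.66), and Foxc1, a transcription factor of niche cells, was at least 14.3-fold higher, with 3.28 for the mean of its probe sets. The lower genes were Bst1 (-4.62, SE 0.52), an ectoenzyme that myeloid cells also carry, and Hp (-3.49, SE 0.27), haptoglobin. The central niche factors Cxcl12 and Lepr differed by 1.36 (SE 1.03) and 0.68 (SE 1.48) and did not pass. By mouse, Cxcl12 differed by 1.84, 3.57 and -1.32 and Lepr by -3.33, 3.69 and 1.69 in mice 1, 2 and 3. The call of this list was lost under 5 of 20 alternatives, among them without mouse 2 (median 1.19, adjusted p = 0.0704), with the stricter filter (median 1.87, adjusted p = 0.0629) and with fry (adjusted p = 0.0530), and the median was 0.84 without the filter. The pan-haematopoietic list on these arrays had median levels of 8.95 to 9.29 in Grem1- and of 4.17 to 5.23 in Grem1+. Of 18 skeletal stem and mesenchymal progenitor genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone), and the list did not pass (median 0.99, camera adjusted p = 0.0802), but it passed without the replicate block (adjusted p = 0.0472) and with fry (adjusted p = 0.0215). Its median was 0.51 without the filter, 2.81 with the stricter filter and 0.65 without mouse 2. Cspg4, the NG2 proteoglycan, differed by 5.40 (SE 0.50), Cd200 by 2.83 (SE 0.34), Pdgfrb by 2.91 (SE 0.64) and Alcam by -3.09 (SE 0.55). The 2 passing probe sets of Cspg4 ranged from 2.36 to 5.40. Pdgfrb was just within the threshold and lost its call under 11 of 18 alternatives, with 1.55 for the mean of its probe sets (adjusted p = 0.0561) and adjusted p-values from 0.0136 to 0.124 over all 18.

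Markers of other non-blood cells showed smaller shifts. Of 14 smooth muscle and pericyte genes, 3 were higher and 0 lower (5 and 0 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.0107, and adjusted p = 0.253 with an estimated correlation). Beside Cspg4, these were Mylk (2.14, SE 0.26) and Tpm1 (1.44, SE 0.29), which encode myosin light chain kinase and a tropomyosin. Mylk lost its call without the replicate block (adjusted p = 0.0653), Tpm1 under quantile normalization (adjusted p = 0.0507), and the list with the stricter filter (median 1.79, adjusted p = 0.0629), while its median was 0.57 without the filter. With its most variable probe set Tpm1 differed by 2.53 (limma adjusted p = 0.0256). Pan-haematopoietic median levels on the same arrays were 8.95 to 9.29 in Grem1- and 4.17 to 5.23 in Grem1+. Of 9 adipocyte genes only Scd1, a fatty acid desaturase that is not restricted to fat cells, was higher (5.54, SE 0.72), 0 were lower, and the counts were the same adjusted over the list alone. The list median was -0.97 (camera adjusted p = 0.251), or -0.61 without mouse 2 and -0.07 without the filter. Of 8 skeletal muscle genes 1 was higher, also when adjusted over the list alone, and 0 lower, namely the troponin gene Tnni2 (3.46, SE 0.61). The list median of 0.22 (camera adjusted p = 0.559) changed sign under median centring and cyclic loess. Of 5 Schwann cell genes 2 were higher, also when adjusted over the list alone, and 0 lower. These were S100b, a gene that cartilage also expresses, at least 69.6-fold higher on 1 of its 2 probe sets (6.86 and 1.80, with 4.33 for their mean), and Pmp22 (4.86, SE 0.75), and the list median was -0.02 although camera pointed up (adjusted p = 0.420). Of 7 endothelial genes 0 were higher and 0 lower at either adjustment, while 3666 of all genes had an unadjusted p under 0.05 in limma. The median was -0.21 (camera adjusted p = 0.202) and ranged from -0.65 with the most variable probe sets to -0.03 without mouse 3, while the list passed without the filter (median -0.15, adjusted p = 0.0150). Tek, an angiopoietin receptor below log2 4 on all Grem1+ arrays, did not pass (adjusted p = 0.0649). With values below log2 4 set to 4 Tek differed by -1.36 (adjusted p = 0.249), and as deposited it passed without the replicate block (adjusted p = 0.0422).

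Genes of growth factor signalling and limb patterning were higher as groups. Of 34 genes of BMP and TGF-beta signalling, 15 were higher and 2 lower (19 and 2 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 2.02e-06, and adjusted p = 0.234 with an estimated correlation). Beside Chrdl1, Bmp2 differed by 5.79 (SE 0.31), Gdf10 by 5.70 (SE 0.30), and Inhbb, an activin subunit, was at least 14.3-fold higher. The lower members were Acvrl1 (-3.81, SE 0.39), a receptor best known from endothelium, and Tgfb1, at least 2.89-fold lower. Of 23 Wnt genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 0.000148, and adjusted p = 0.253 with an estimated correlation). The secreted antagonists Frzb and Wif1 were at least 42.1-fold and 43.8-fold higher. Lgr6 was at least 7.80-fold higher on 1 of its 2 passing probe sets, and Tcf7l2 differed by 2.82 (SE 0.46). Probe sets ranged from 1.20 to 3.47 for Lgr6 and from 1.39 to 2.82 for Tcf7l2. Of 25 genes of FGF, IGF, PDGF and Hedgehog signalling, 13 were higher and 0 lower at either adjustment, all genes or adjusted over the list alone, with a median of 2.40 (camera adjusted p = 8.07e-06, and adjusted p = 0.234 with an estimated correlation). Ptch1, a receptor and target of Hedgehog, differed by 5.75 (SE 0.73), Fgfr2 by 5.65 (SE 0.26), Fgf2 was at least 47.2-fold higher and Hhip, another Hedgehog target, at least 21.9-fold. Of 12 HOX and limb genes, 7 were higher and 0 lower at either adjustment, all genes or adjusted over the list alone, with a median of 3.62 (camera adjusted p = 0.000295, and adjusted p = 0.234 with an estimated correlation). Shox2 was at least 37.8-fold higher, and Hoxd8, Tbx15 and Hoxc10 differed by 5.17 (SE 0.29), 4.82 (SE 0.33) and 4.29 (SE 0.60). With every value below log2 4 set to 4 the HOX median was 2.62, and without the filter the HOX, Wnt and FGF list medians were 0.36, 0.32 and 1.47, all still past the threshold. With the stricter filter the Wnt median was 2.67. Fgfr2 lost its call without shared probe sets (4.06, adjusted p = 0.0520). The median level of the pan-haematopoietic list on the same arrays was 8.95, 9.17 and 9.29 in Grem1- and 4.70, 4.17 and 5.23 in Grem1+.

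Secreted factors split in both directions. Of 11 cytokine and chemokine genes, 4 were higher and 2 lower (5 and 4 adjusted over the list alone), and the list did not pass (median 1.42, camera adjusted p = 0.251). The median was 0.77 without mouse 3, 0.12 without the filter and 2.61 with the stricter filter, and the list passed with fry (adjusted p = 0.00967). Cxcl14 was at least 42.3-fold higher, Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, differed by 5.43 (SE 0.33) and Il11 by 5.17 (SE 0.36). Ccl9, a chemokine of myeloid cells and osteoclasts, differed by -4.06 (SE 0.47) and Il1b by -2.10 (SE 0.26). The pan-haematopoietic median difference on these arrays was -3.29.

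Several lists of blood cell genes were lower in Grem1+ as groups. Of 22 pan-haematopoietic genes, 0 were higher and 18 lower (0 and 22 adjusted over the list alone), with a median of -3.29 (camera adjusted p = 9.14e-12, and adjusted p = 0.234 with an estimated correlation). Ikzf1, a lymphoid transcription factor, differed by -5.33 (SE 0.51), Vav1 by -4.46 (SE 0.46), Fcer1g by -4.42 (SE 0.35) and Cd52 by -4.20 (SE 0.29). Of 23 granulocyte and neutrophil genes, 0 were higher and 17 lower (0 and 22 adjusted over the list alone), with a median of -3.00 (camera adjusted p = 5.17e-11, and adjusted p = 0.253 with an estimated correlation). The granule genes Mmp8, Ctsg, Fcnb and Lcn2 differed by -5.73 (SE 0.52), -5.68 (SE 1.11), -5.14 (SE 0.26) and -4.99 (SE 0.85). Of 19 erythroid genes, 1 was higher and 11 lower (1 and 13 adjusted over the list alone), with a median of -2.73 (camera adjusted p = 5.81e-07, and adjusted p = 0.253 with an estimated correlation). Beside Hemgn and Car2, Slc4a1, the band 3 anion exchanger, differed by -5.83 (SE 0.26) and Ermap by -5.26 (SE 0.55), and the higher gene was the metallothionein Mt2 (2.43, SE 0.40), which many cells express. Of 14 B lineage genes, 0 were higher and 7 lower (0 and 10 adjusted over the list alone), with a median of -1.93 (camera adjusted p = 2.09e-06, and adjusted p = 0.234 with an estimated correlation). Beside Vpreb1, Ighm differed by -4.94 (SE 0.93), Dntt, the terminal transferase of lymphoid precursors, was at least 13.2-fold lower and Cd79b at least 3.49-fold lower. Without the filter the B lineage median was -1.10, and with the stricter filter the B lineage and erythroid medians were -4.10 and -4.74. Without shared probe sets Dntt differed by -1.88, and with the mean of its probe sets Ikzf1 differed by -3.50.

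Other blood lists were less uniform. Of 20 monocyte, macrophage and dendritic genes, 0 were higher and 7 lower (0 and 8 adjusted over the list alone), with a median of -1.73 (camera adjusted p = 1.08e-05, and adjusted p = 0.339 with an estimated correlation). This median was -1.10 without the filter and -3.27 with the stricter filter, and the call was lost with fry (adjusted p = 0.0530). Mpeg1 differed by -4.93 (SE 0.80), Slc40a1, the iron exporter ferroportin, by -4.09 (SE 0.53), Csf1r by -3.75 (SE 0.79) and Fcgr3 by -3.49 (SE 0.38). The 3 probe sets of Csf1r ranged from -3.75 to -0.20 with -1.89 for their mean, and Csf1r lost its call under cyclic loess (adjusted p = 0.0549) and without the filter (adjusted p = 0.107). Of 6 mast cell and basophil genes, 0 were higher and 2 lower at either adjustment, all genes or adjusted over the list alone, with a median of -1.66 (camera adjusted p = 0.0471, and adjusted p = 0.295 with an estimated correlation). Mcpt8 differed by -2.84 (SE 0.27) and Kit, the stem cell factor receptor, was at least 1.87-fold lower. With values below log2 4 set to 4, Kit was no longer called (adjusted p = 0.229), nor was the list (median -0.66, adjusted p = 0.0751), and the list lost its call under 8 of 19 alternatives in all, among them without mouse 2 (median -1.30, adjusted p = 0.117) and without shared probe sets (median -0.72, adjusted p = 0.0924). Its median was -0.32 without the filter. Of 10 osteoclast genes, 1 was higher and 3 lower (2 and 3 adjusted over the list alone), and the list did not pass (median -0.74, camera adjusted p = 0.202), with a median of -0.31 without mouse 1 and -0.14 without the filter. Nfatc1 was higher by 2.97 (SE 0.26), a call lost with its most variable probe set (4.77, adjusted p = 0.0540), and Car2, Mmp9 (-4.86, SE 0.51) and Itgb3 were lower. The 5 passing probe sets of Nfatc1 ranged from -0.66 to 4.77. Of 9 megakaryocyte genes, 0 were higher and 3 lower (1 and 4 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.172), or -1.07 without mouse 1, -0.17 without mouse 2 and 0.08 without mouse 3. Pf4, platelet factor 4, differed by -2.96 (SE 0.49), and Gata1 was at least 1.90-fold lower but lost its call with the floor at log2 4 (adjusted p = 0.125). Of 10 T and NK cell genes, 0 were higher and 1 lower (0 and 0 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.110), which passed at -0.71 without mouse 2 (adjusted p = 0.0420) and was -0.16 without mouse 1. The lower gene was Nkg7, at least 1.54-fold, whose call was lost with the floor (adjusted p = 0.169). Of 14 haematopoietic stem and progenitor genes, 2 were higher and 3 lower at either adjustment, all genes or adjusted over the list alone, and the list did not pass (median -0.32, camera adjusted p = 0.223), with a median of -0.56 without mouse 2 and -0.20 without mouse 3. Lmo2 and Myb, transcription factors of progenitors, differed by -5.14 (SE 1.01) and -5.06 (SE 0.45), and Hoxa9 and Procr by 4.28 (SE 0.62) and 2.80 (SE 0.50).

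**Figure D3:**
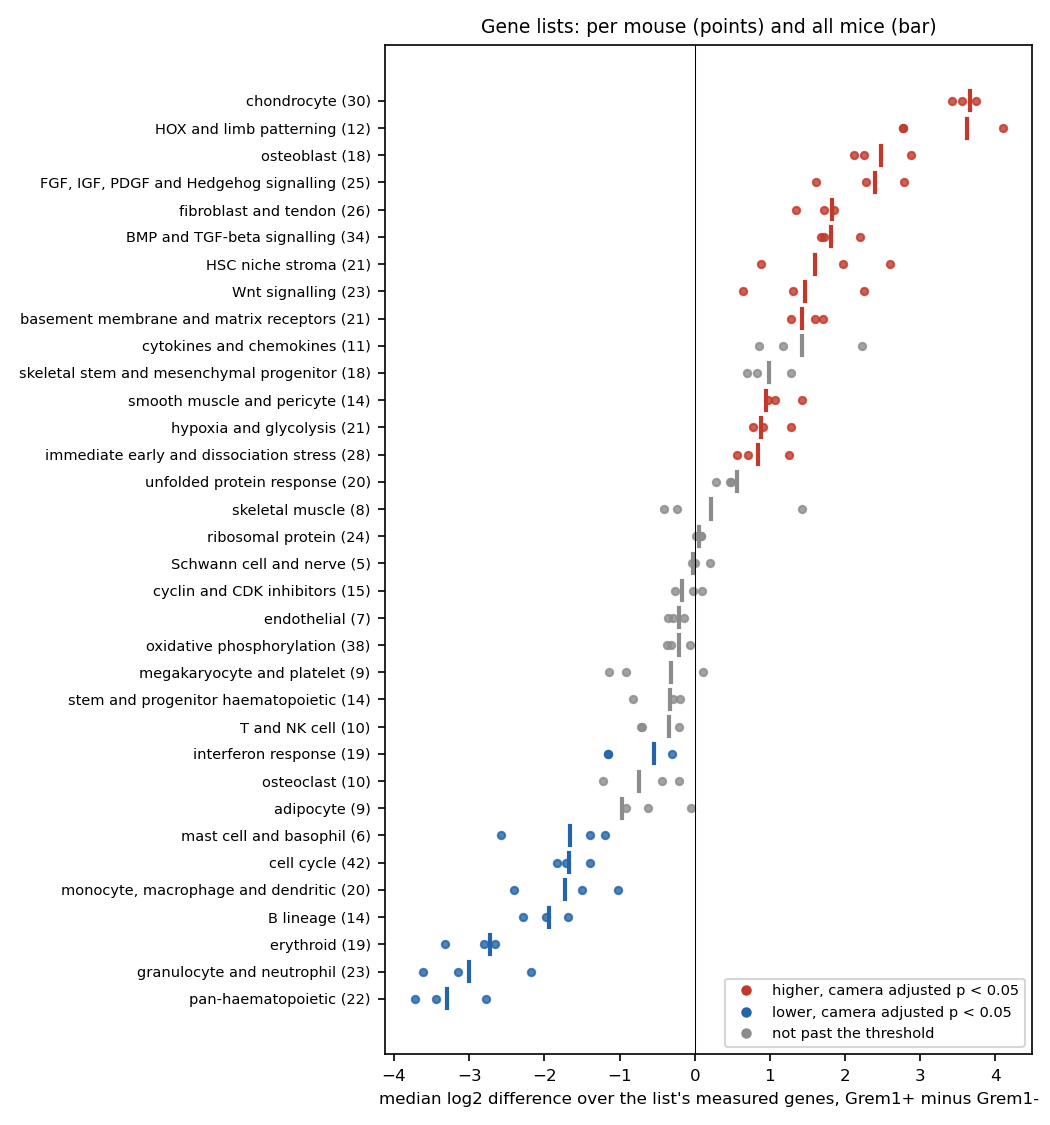
Median log2 difference of Grem1+ minus Grem1- (x axis) over the measured genes of each of the 34 lists (y axis, number measured in brackets), with a point for each of 3 mice and a bar for all mice. Red and blue lists passed camera at its preset correlation, 12 higher and 8 lower. With an estimated correlation, where 2 residual degrees of freedom let few lists pass, 0 lists passed.

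Of 42 cell cycle genes, 0 were higher and 17 lower (0 and 25 adjusted over the list alone), with a median of -1.67 (camera adjusted p = 3.49e-11, and adjusted p = 0.234 with an estimated correlation). The replication genes Mcm2 and Cdc6 were at least 16.6-fold lower and lower by a difference of -4.40 (SE 0.50). The mitotic genes Nusap1 and Kif11 differed by -3.63 (SE 0.40) and -3.44 (SE 0.39). The 3 passing probe sets of Kif11 ranged from -3.44 to -1.27. Without shared probe sets Mcm2 stood at -2.02 and lost its call (adjusted p = 0.0599). Of 15 cyclin and CDK inhibitor genes, 3 were higher and 3 lower (3 and 5 adjusted over the list alone), and the list did not pass (median -0.17, camera adjusted p = 0.737). Cdkn1c and Ccnd1, a CDK inhibitor and cyclin D1, differed by 4.55 (SE 0.42) and 4.38 (SE 0.70), and Cdkn1b and Rbl1 by -2.59 (SE 0.41) and -2.23 (SE 0.31). The 3 passing probe sets of Ccnd1 ranged from 1.35 to 4.38. Rbl1 lost its call with its most variable probe set, where it differed by -2.73 (adjusted p = 0.106). On the same arrays Ptprc was at 12.09 in Grem1- and 9.15 in Grem1+.

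Stress genes were higher in part. Of 28 immediate early genes, a group that tissue dissociation can induce, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.000197, and adjusted p = 0.253 with an estimated correlation). Egr3 differed by 5.09 (SE 0.61), Ccn1 by 4.04 (SE 0.38), Myc by 3.15 (SE 0.57) and Hspb1 by 2.92 (SE 0.33). Of 21 hypoxia and glycolysis genes, 8 were higher and 0 lower (9 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.000837, and adjusted p = 0.253 with an estimated correlation). The collagen prolyl hydroxylase genes P4ha2 and P4ha1 differed by 5.59 (SE 0.41) and 2.64 (SE 0.34), Bnip3 by 4.09 (SE 0.74) and Ndrg1 by 2.09 (SE 0.41). With the most variable probe set of each gene, the medians of these lists were 1.56 and 1.42, and P4ha1 stood at 3.20 but lost its call (adjusted p = 0.0690). Without shared probe sets Ndrg1 stood at 1.84 and lost its call (adjusted p = 0.0818). Of 20 unfolded protein response genes, 2 were higher and 0 lower at either adjustment, all genes or adjusted over the list alone, and the list did not pass (median 0.56, camera adjusted p = 0.0653). Pdia4 differed by 3.58 (SE 0.59), and Pdia6 by 1.45 (SE 0.25) on one probe set and by -1.44 on the other. Of 19 interferon response genes, 0 were higher and 6 lower (0 and 7 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.00101, and adjusted p = 0.259 with an estimated correlation). This median was -0.90 without mouse 1 and -1.91 with the stricter filter, and the call was lost with fry (adjusted p = 0.0794). Oasl2 differed by -3.39 (SE 0.48), the immunoproteasome genes Psmb9 and Psmb8 by -3.14 (SE 0.45) and -2.81 (SE 0.48), and Rsad2 by -2.40 (SE 0.47), which lost its call without the block (adjusted p = 0.0607). On the same arrays as these 4 lists, the pan-haematopoietic median difference was -3.29, and Ptprc was at 12.09 in Grem1- and 9.15 in Grem1+. The Gapdh 3' minus 5' difference was 3.58 in Grem1+ against 2.66 in Grem1- on these arrays.

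Housekeeping lists did not pass. Of 38 oxidative phosphorylation genes 0 were higher and 0 lower at either adjustment in limma, with a median of -0.21 (camera adjusted p = 0.172), or -0.32 without mouse 3. Sdhc and Ndufv1 differed by -1.45 (SE 0.44) and -1.28 (SE 0.63), or by -0.93 and -0.46 without mouse 1. Of 24 ribosomal protein genes 0 were higher and 0 lower, also adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.679), or 0.11 without mouse 1, and Rps6 and Rplp0 differed by 1.03 (SE 0.29) and 0.67 (SE 0.25). Rps6 passed without the replicate block (adjusted p = 0.0359). The median difference over all genes was 0.04.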

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

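Leaving out a mouse without the block was added after seeing the data, and all other alternatives were chosen before. The counts of 1191 higher and 864 lower genes became 1465 and 1078 with no replicate block, and this fit kept 93.6% of the calls. They stayed within 1.5 times under the other normalizations, the floor, the stricter filter, the mean or most variable probe set, variance and weight settings. With no filter 500 genes were lower, since 18193 genes were then tested, and all probe sets together gave 1826 higher and 1409 lower probe sets. Leave-one-out fits with the block gave 0 to 0 higher and 0 to 0 lower genes, as 1 residual degree of freedom was left. Without the block, leaving out mouse 1, 2 or 3 gave 767, 764 and 769 higher and 507, 422 and 525 lower genes and kept 53.6, 50.6 and 54.8% of the calls. Ptprc, at -2.94, passed with no replicate block, with the stricter filter and with a variance trend, and stood at -4.31 with the mean of its probe sets and -5.67 with the most variable one, where it also passed but its Grem1+ arrays were all below log2 4, so that only a difference of -4.85 or beyond can be stated. Pecam1, at -1.50, passed with no replicate block, with the mean of probe sets (where only the other genes change) and with a variance trend. Grem1 passed under none of 17 alternatives and stood between 0.60 and 2.86. The stricter filter left no value for Grem1 and Pecam1. With an estimated correlation 0 lists were higher and 0 lower, and with fry 23 lists passed, but the niche stroma, monocyte and interferon lists lost their call while the skeletal stem, Schwann cell, megakaryocyte, stem and progenitor, unfolded protein response and cytokine lists gained one. With no filter the endothelial, T and NK cell, megakaryocyte, unfolded protein response and oxidative phosphorylation lists also passed camera.

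Among lists and named genes some directions turned, all of them values that had not passed as lists or that rest on 1 probe set. The cause was not tested. The skeletal muscle median was 0.0797 (camera down) with no filter, -0.0456 with the most variable probe set, -0.0917 with median centring, -0.105 with cyclic loess and 0.0296 to 0.441 with a mouse left out. The Schwann cell median was 0.0552 with the floor, 5.93e-05 with array weights and -0.133 to 0.0829 with a mouse left out, and the megakaryocyte median was -1.07 to 0.0805 with a mouse left out. With the stricter filter the stem and progenitor median was 0.0581 and that of cyclins and CDK inhibitors 0.626. Pdia6 was at -1.44 with its most variable probe set. Over all genes, 2046 of the 2055 calls kept their sign with the most variable probe set. Of the 1831 calls shared with that setting, 1829 had the same direction. Of 4624 genes with several passing probe sets, 3 had probe sets called in opposite directions. Of 2238 values of 125 named genes under alternatives, 1735 kept direction and side of the threshold, 497 lost the threshold, 5 gained it and 1 turned. Each fit that left out a mouse with the block kept made up 120 of these losses, since 0 genes pass there. Leaving out mouse 1, 2 or 3 without the block made up 27, 34 and 23, and dropping the filter 31. A slide or scan block and another background correction were not run, since no scanner files were used here. Dim signals limit what a fold can say, and bounds against log2 4 were given for that reason.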

Other observations

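The tests of dilution among stromal genes, of normalization and dim values and of blood cells in the Grem1- fraction were chosen after seeing the results. So were the families described next. The test of sex-linked genes was prompted by Xist values already seen, and the splits were chosen before the results. Of 34 measured genes that build glycosaminoglycan chains, the sulfated sugars of cartilage matrix, 15 were higher and 1 lower, with a median of 1.68 (camera adjusted p = 1.62e-06 over 6 families, and adjusted p = 0.145 with an estimated correlation), and 2 of the 34 are also in a list of the report. Chsy3 and Csgalnact1, which start or extend chondroitin chains, differed by 6.34 (SE 0.63) and 6.10 (SE 0.55), Hs3st3b1 by 6.18 (SE 0.43), and the sulfate transporter Slc26a2 by 4.74 (SE 0.49), and the hyaluronan synthase Has2 was at least 22.9-fold higher. The lower gene was Chst13 (-2.61, SE 0.38). Of 13 core proteins that carry such chains, 7 were higher and 1 lower, with a median of 2.88 (camera adjusted p = 0.0119, and adjusted p = 0.182 with an estimated correlation). Gpc6 and Sdc4 differed by 5.99 (SE 0.46) and 4.85 (SE 0.56), and the lower gene was Srgn (-2.60, SE 0.45), the serglycin of blood cell granules.

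Of 30 collagen chains, 21 of them also in a list of the report, 18 were higher and 0 lower (median 2.71, camera adjusted p = 1.27e-07, and adjusted p = 0.145 with an estimated correlation), Col12a1 by 4.88 (SE 0.33). Of 11 Adamts and Adamtsl genes, 3 were higher and 0 lower (median 0.74, camera adjusted p = 0.0195, and adjusted p = 0.182 with an estimated correlation), among them Adamts1 by 3.88 (SE 0.51). Of 10 serpins, 3 were higher and 1 lower (median 0.10, camera adjusted p = 0.422). Serpina1b differed by 5.19 (SE 0.31) and Serpinb1a, an inhibitor of neutrophil proteases, by -6.04 (SE 0.49). Of 175 solute carriers, 38 were higher and 18 lower (median 0.30, camera adjusted p = 0.0472, and adjusted p = 0.208 with an estimated correlation). The medians of the first 5 families kept their sign under quantile normalization, median centring, cyclic loess, the floor and with each mouse left out. On the same arrays the pan-haematopoietic median difference was -3.29.

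The higher chondrocyte genes were weighed against dilution, normalization and dim values. If blood-cell RNA in the Grem1- fraction diluted stromal RNA of every kind alike, stromal lists would shift together. The chondrocyte median difference exceeded that of 5 other stromal lists pooled by 2.13 ± 0.11 (SD, 3 mice). It exceeded that of the osteoblast list, the closest of these, by 1.16 ± 0.25 (0.87 in mouse 1). The HOX and limb list lay only 0.36 ± 0.79 away. Lists with lower levels in Grem1+ have less room to fall. The osteoblast list had median levels of 7.68 in Grem1+ and 4.56 in Grem1-, against 11.08 and 6.95 for the chondrocyte list. Equal dilution down to a floor could leave such a gap, so the gaps do not decide against dilution as the whole cause. Collagen chains of similar Grem1+ level with Grem1- means above log2 4 differed unequally. Col1a1, Col3a1 and Col1a2, at 10.18, 10.52 and 11.00 in Grem1+, differed by -0.04 (SE 0.38), -0.04 (SE 0.29) and 0.42 (SE 0.28). Col5a1, Col12a1 and Col6a1, at 10.18, 10.47 and 10.68, differed by 2.94 (SE 0.32), 4.88 (SE 0.33) and 5.01 (SE 0.25). In the chondrocyte list Col2a1 and Col27a1, at 12.04 and 12.12, differed by 0.52 (SE 0.26) and 2.88 (SE 0.36). With the floor or without the filter the lowest chondrocyte median was 3.46, which argues against dim values as the cause. The 3 other normalizations gave at least 3.63 but moved the median of all genes by at most 0.0286, too little to test normalization. A shift of whole arrays would move all lists in the same direction. The chondrocyte median was 3.66, the pan-haematopoietic median -3.29 and the ribosomal protein median 0.06, which argues against such a shift as the cause. Other effects of normalization stay open with the background correction. A hypothesis that stays open is that Grem1+ cells are richer in cells with a cartilage programme. A different mix of stromal cells in Grem1- may account for the higher chondrocyte genes as well. Dilution may account for part of each difference, since the other stromal lists had a median of 1.44. Equal dilution would shift collagen chains of similar Grem1+ level alike. Their unequal differences argue against it as the whole cause for these genes. For the rest of the chondrocyte list, dilution as the whole cause stays open.

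Blood genes were abundant in the Grem1- fraction although it was gated against CD45 and Ter-119. Precursors that lack CD45 alone would leave Ptprc low, yet on every Grem1- array its probe sets were at 11.78 or above and at 8.37 or above, which argues against them as the only source. These levels are consistent with CD45-bearing blood cells, or their free RNA, in that fraction, and the erythroid list had medians of 8.48, 9.63 and 7.81 there. In Grem1+ the Ptprc probe sets differed, with 7.29 to 10.56 for one and below log2 4 on every array for the other, so the same source was not settled for that fraction. There the granulocyte list had median levels of 4.98, 5.95 and 7.11 in mice 1, 2 and 3, and the B lineage list 4.05, 4.14 and 4.02. Granulocyte transcripts were thus measured in Grem1+ too, most in mouse 3, and their source was not tested. Protein and transcript were not compared, so the gate itself was not tested.

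Xist was above log2 10 in both fractions of mouse 3 and below 3 in mice 1 and 2, while the labels give all animals as male. The 3 named Y-linked genes Eif2s3y, Kdm5d and Uty averaged 2.68 and 2.71 in the fractions of mouse 3, and 8.23, 7.64, 4.84 and 7.32 on the other arrays, so the lowest of these lay 2.13 above the highest of mouse 3. On that lowest array, Grem1+ of mouse 1, Eif2s3y stood at 7.98, but Kdm5d at 3.75 and Uty at 2.80 were dim. The gap there rests on Eif2s3y, which stood at 3.08 and 3.42 in mouse 3. Ddx3y was also sought but had no probe set with 1 symbol. Male cells mixed with female cells would keep the Y-linked signal, and this gap of 2.13 argues against that. The values are consistent with a female mouse 3, and both fractions having it fits the pairing in the design text. Sex was not tested as an influence on other genes, because 1 animal carries it. The block removes only an influence that both fractions of a mouse share. An influence on the difference between the fractions would stay in the comparison and cannot be told from other differences between mice.

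The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many as 2055 genes past the threshold, and the highest of the others gave 0. Every other split has arrays of both fractions on each side, so the difference between the fractions enters its residual spread. Low counts in the other splits are thus built in, and the splits do not decide whether the calls arose by chance. At an unadjusted p under 0.05 the real split gave 3666 genes and the highest other 423. Of the 10 splits 4 part all 3 pairs, and the others among these also gave 0, while the remaining splits part 1 pair. With the block, a split that parts 1 pair takes its difference from that pair alone, which is Grem1+ against Grem1- in 1 mouse. The 423 genes came from splits that part the pair of mouse 1, so they are no count for arrays without a difference. Without the block the real split gave 2543 and the highest other 0.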
